A study of Drosophila melanogaster with 24 samples.

How the data were processed

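Whole-fly RNA of Drosophila melanogaster was measured on 24 NimbleGen oligonucleotide arrays. Per the labels, each array held Cy3-labelled cDNA, amplified from the total RNA of a pool of about 35 female flies aged 13 days. The flies carried 1 copy each of a GeneSwitch driver under Act5c control, which is active only when the flies are given the drug RU486, and of the RNAi insertion P{GD3482}v8105. From general knowledge of this collection and not from the labels, that insertion targets ACC, the acetyl-CoA carboxylase of fatty acid synthesis. The 4 groups were AL without RU486, AL with RU486, DR without RU486 and DR with RU486, with 6 pools each. DR is dietary restriction, for 10 days per the labels. The labels do not spell out AL, and it is used here as the name of the other diet. Extraction, amplification and labelling were randomized over the groups, per the labels' protocols.

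The deposited values are log2 brightness per probe, a base taken from their range of 6.09 to 16.51, with 137090 probes and 0 missing values. The submitters' processing notes name limma, with no version. The background correction, the normalization method and the log base were not given in the sources used here. Array medians over all probes lay between 9.26 and 9.47. Below the brightest 100 ranks the arrays' sorted values differed by up to 0.38, so the values had not been made identical in distribution. The values were used as given. The slide of each array was not given in the sources used here, so no slide or date could be entered as a batch.

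Of the probes, 4091 are random control probes and 132999 belong to 16637 transcripts, which are identified by FlyBase transcript numbers. Most transcripts, 16617, have 8 probes. A transcript's value is the mean log2 value of its probes. Each array's background is the 95th percentile of 511 sets of 8 random probes averaged in the same way. Between 12945 and 14350 transcripts per array lay above it, and 1380 lay above it on no array. The transcript numbers were looked up in a table of RefSeq genes of assembly Release 6. It gave 1 gene symbol for 16 transcripts and several for 28, and 16593 stayed unnamed. No transcript with several symbols is named. No gene coordinates are printed because the build of the array design was not given in the sources used here.

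Comparisons were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with 1 mean per group over all 24 arrays, and p-values were adjusted by the Benjamini-Hochberg method over all transcripts at a threshold of 0.05. The contrasts were diet without RU486, diet with RU486, RU486 on AL, RU486 on DR, their interaction, and the average effects of diet and of RU486. Effects were compared across transcripts with Pearson's r and Spearman's rho, only between contrasts that share no arrays or are orthogonal. Transcripts are not independent replicates. A position on the diet axis was computed for each array as the projection of its difference from the AL mean on the DR minus AL difference, with the array itself left out and without use of the RU486 labels. Positions were compared by exact two-sided permutation tests over 924 splits, whose smallest possible p is 0.0022. The axis, and the correlations of the average diet effect with the RU486 effect on each diet, were added after the data were seen. Figures were drawn with matplotlib 3.10.9.

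The rule for naming was fixed before the data were examined. In files without gene names it takes, for each contrast, the 2 transcripts with the highest and the 2 with the lowest log2 fold change among those past the threshold with a mean above the 25th percentile. These are given by identifier. The 16 transcripts with 1 symbol are described in addition. They were picked by the lookup and not by their values, and they are no pathway or functional group. The 31 gene lists fixed beforehand held 0 of them, so no gene list was tested, and the transcript of ACC was not analysed here. The knockdown was therefore not checked at its target. Flies of all groups carried the transgene, and those given the drug also had it switched on. The effects of the drug and of the switched-on transgene cannot be told apart in these groups. Where 1 or more arrays of the dimmer group lay below background, that group has only an upper bound, and the difference is then given as at least N, in fold or log2. It sets the bright group's mean against the mean, over the dim group's arrays, of the higher of the background and the transcript's own value.

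The procedure was tested on simulated data with changes added to 200 of the 16637 transcripts. For RU486 on DR it recovered 86 of 100 changes of 0.5 log2 and 98 of 100 changes of 1 log2, with 6 false calls. For the interaction it recovered 62 and 96 of 100, with 7 false calls. The simulated noise was independent between transcripts and had the same spread on every array. Real arrays differed in spread, with SDs of transcript deviations from 0.101 to 0.365 log2, and many more transcripts changed. These rates need not hold for the real arrays. No 2 arrays held identical values, and the highest correlation between arrays was 0.997. The labels number the pools 1 to 6 in every group without saying that a number marks a shared batch. Precision is limited by the number of arrays, 6 per group. Pools are separate samples by their labels, and p-values measure the spread between these pools. Alternatives tried were quantile normalization, centring on array medians, medians over probes, tests of single probes, filters on dim transcripts, fits of only the groups compared, the replicate block, array weights, a mean-variance trend with robust hyperparameters, and leaving out each array. In tests of single probes, p-values were adjusted over all probes, and a transcript counted by the share of its probes that passed in 1 direction. Added after the data were seen were leaving out the arrays AL with RU486 pool 1 and DR with RU486 pool 3 together, and keeping only transcripts above background.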

Results

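RNA from pools of whole female flies was profiled on 24 arrays in a design of 2 diets, AL and DR, each with and without RU486, with 6 pools per group. RU486 switches on a ubiquitous driver and with it an RNAi transgene. On AL arrays without RU486, 13392 ± 242 transcripts (SD, n = 6) lay above the background set by random probes, and on DR arrays without RU486 the number was 14259 ± 86.4. With RU486 the numbers were 13290 ± 203 on AL and 13926 ± 231 on DR. The background was set on each array, at a mean of 7.57 log2 on AL and 7.37 on DR without RU486 and of 7.58 and 7.49 with it, so these numbers do not share 1 threshold. Array AL with RU486 pool 1 stood apart from its group, with an SD of transcript deviations of 0.365 log2 against 0.110 to 0.140 in the other pools. Array DR with RU486 pool 3 had an SD of 0.228 against 0.119 to 0.159 in its group. Every transcript named by identifier below has no gene name in the table used here.

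The first comparison asked how the flies' transcripts differ between diets without RU486. On DR, FBtr0085029 rose from 8.21 ± 0.65 to 13.61 ± 0.37 log2 (SD, n = 6), or 42.2-fold. FBtr0077061 rose at least 26.6-fold, with AL arrays below background set to it, and was above background on 2 of 6 AL arrays and 6 of 6 DR arrays. FBtr0089324 fell by at least 4.94 on the log2 scale and FBtr0089326 by at least 4.54, each to 5 of 6 DR arrays above background. Among the 16 transcripts with a gene symbol, 4 rose, 6 fell and 6 did not pass, and the same number, 10, passed when adjusted over the list alone. Fatp1, a fatty acid transport protein, rose by 0.58 ± 0.08 log2 (SE, adjusted p = 3.89e-07), and LanA, the laminin alpha chain of basement membranes, by 0.72 ± 0.08 (adjusted p = 2.13e-08).

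The spectrin alpha-Spec, of the membrane skeleton, rose by 0.64 ± 0.12 log2 (SE). The histone H4 gene His4r rose by 0.31 ± 0.10, a call that was lost after quantile normalization (adjusted p = 0.071) and after centring on array medians (adjusted p = 0.10). Wdr24, a subunit of the GATOR2 complex that acts on TORC1 signalling, fell by 0.62 ± 0.10 log2 (adjusted p = 3.91e-06). The nucleolar protein gene sle fell by 0.41 ± 0.06, the histone deacetylase gene HDAC3 by 0.41 ± 0.07 and fend by 0.47 ± 0.15. SuUR fell by 0.34 ± 0.08, and CG16974 by 0.23 ± 0.05. For mio, another GATOR2 subunit, the difference was −0.12 ± 0.08 log2 (adjusted p = 0.18), and mio passed after quantile normalization (adjusted p = 0.012), after centring (adjusted p = 0.0059) and without the 2 arrays that stand apart (adjusted p = 0.041). The transcripts kis, Uba1, NaPi-III and rdx had differences of −0.08, −0.06, −0.10 and −0.03 log2 and did not pass. Both kis and Uba1 passed after quantile normalization (adjusted p = 0.046 and 0.012). After centring, kis, Uba1 and NaPi-III passed (adjusted p = 0.0038, 0.014 and 0.022), as did CG31178, which was above background on 0 arrays.

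In all, 10860 of 16637 transcripts passed for diet without RU486 in limma, 4946 higher and 5914 lower on DR. At a change of at least 1.5-fold, 2473 rose and 735 fell, and at 2-fold 1047 rose and 90 fell. With single probes tested, 3967 rose and 3548 fell. The split of calls also depends on the centring of the arrays. After centring on array medians 3984 rose and 8758 fell, with the median of all transcripts at −0.20 log2 against −0.07 as deposited. Of the calls, 611 were transcripts above background on no array, and 609 of these were lower on DR, where the random probes were lower too, by −0.16 log2 at their median (exact permutation p = 0.0022, the smallest possible).

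With RU486 the identifiers named for diet were the same 4 as without it. FBtr0085029 rose by 4.75 ± 0.26 log2 (SE) and FBtr0077061, above background on 3 of 6 AL arrays, by at least 4.41, while FBtr0089324 fell by 4.60 ± 0.22 and FBtr0089326 fell by 4.53 ± 0.17. Of the 16 transcripts with a symbol, 2 rose, 4 fell and 10 did not pass, and 6 passed when adjusted over the list alone. Fatp1 rose by 0.52 ± 0.08 log2 (adjusted p = 3.43e-06) and LanA by 0.47 ± 0.08. The genes that fell were fend by 0.61 ± 0.15, Wdr24 by 0.50 ± 0.10, sle by 0.32 ± 0.06 and SuUR by 0.26 ± 0.08. The difference of alpha-Spec was 0.13 ± 0.12 log2 (adjusted p = 0.38), and it passed at 0.26 without pool 3 of the DR group given RU486 (adjusted p = 0.025), at 0.34 without the 2 arrays that stand apart (adjusted p = 0.00089) and at 0.28 with array weights (adjusted p = 0.0034). After centring, kis, mio, HDAC3 and Uba1 passed as lower (adjusted p = 0.014, 0.033, 0.0496 and 0.035), as did CG31178 (adjusted p = 0.018), and Uba1 also with array weights (adjusted p = 0.033). In total 8116 transcripts passed in limma, 4074 higher and 4042 lower on DR. At 1.5-fold, 1648 rose and 328 fell, and at 2-fold 456 rose and 78 fell. After centring on array medians 3355 rose and 6749 fell. With single probes tested, 2993 rose and 1699 fell.

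The diet effects without and with RU486, which share no arrays, had a Pearson's r of 0.905 and a Spearman's rho of 0.839 across 16637 transcripts, which are not independent replicates. Both tests passed in the same direction for 3750 transcripts that rose and 3200 that fell, against 1211 and 1437 for independent lists. Another 27 transcripts, 19 and 8, passed in opposite directions. The slope of the effect with RU486 on that without, corrected for noise, was 0.721.

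**Figure D1:**
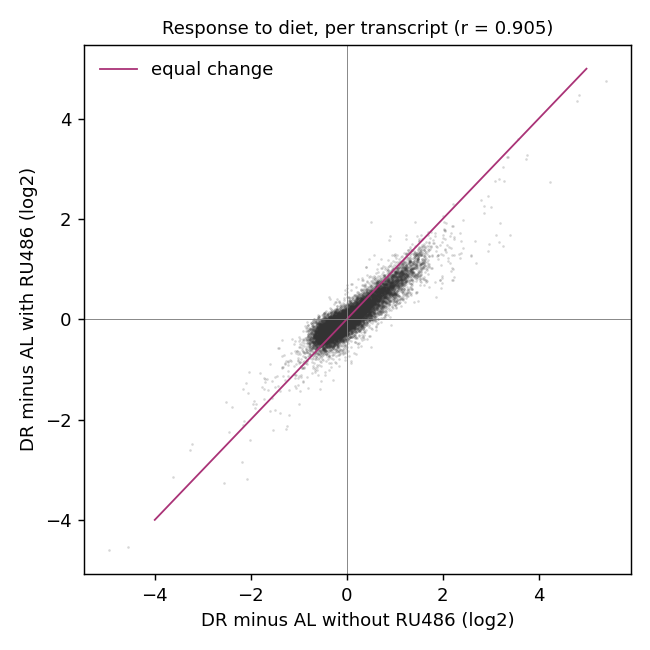
Each point is 1 of 16637 transcripts, with the DR minus AL difference in log2 without RU486 on the horizontal axis and with RU486 on the vertical axis. The line marks equal change, and Pearson's r is 0.905.

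**Figure D2:**
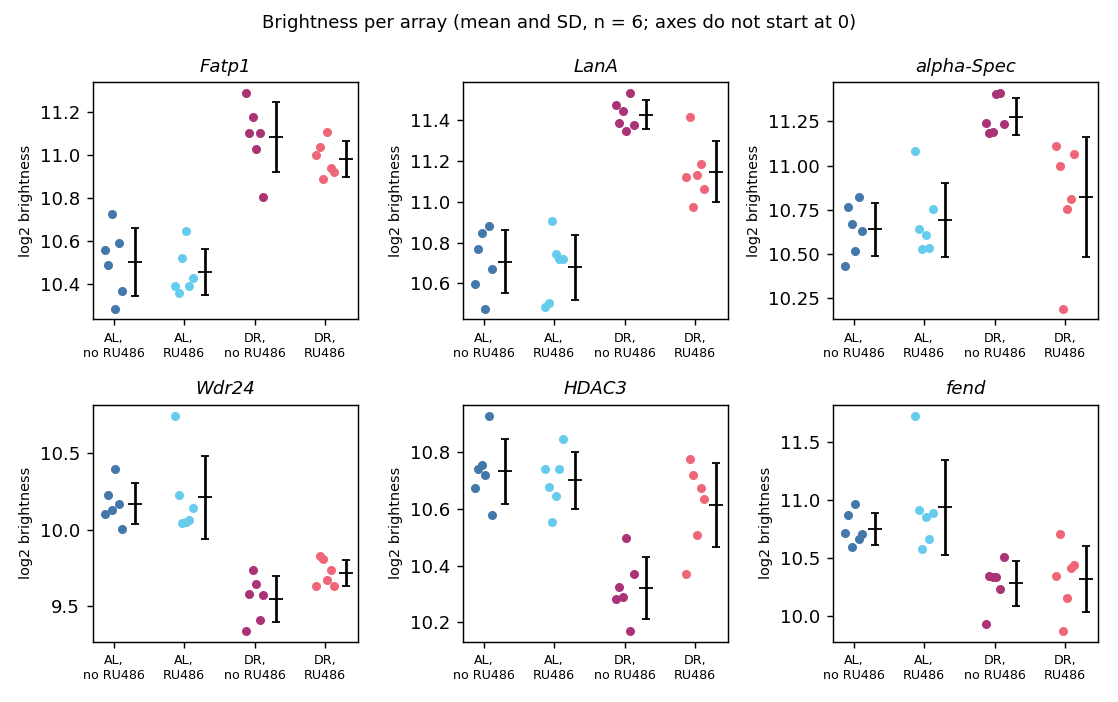
Log2 brightness of 6 transcripts with a gene symbol on each of the 24 arrays, by group, with mean and SD (n = 6), on axes that do not start at 0. LanA and alpha-Spec are lower on DR with RU486 than on DR without it, and AL with RU486 pool 1 is the highest array of its group for fend and Wdr24.

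The comparison of AL flies with and without RU486 asked what the inducer does on the first diet. FBtr0070490 rose by 1.29 ± 0.07 log2 (SE, adjusted p = 1.71e-11), or 2.44-fold, and FBtr0073651 by 1.25 ± 0.18. FBtr0080237 fell from 9.05 ± 0.20 to 7.27 ± 0.12 log2 (SD, n = 6), a value above background on 0 of 6 arrays, and so was at least 2.78-fold lower. The first 3 of its 8 probes, with means of 6.89, 7.16 and 7.68 log2 and so little signal to lose, moved by 0.02, −0.36 and −0.45 log2. The other 5, with means of 9.49 to 9.87, moved by −2.49 to −2.83. FBtr0072764 was at least 1.98-fold lower and also above background on 0 of 6 arrays with RU486. None of the 16 transcripts with a symbol passed in limma, over all transcripts or adjusted over the list alone, with Fatp1 at −0.05 ± 0.08 log2 and fend at 0.18 ± 0.15, or 0.02 without pool 1 of the AL group given RU486.

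In total 104 transcripts passed for RU486 on AL, 48 higher and 56 lower, or 13 and 20 at 1.5-fold, and 1406 had an unadjusted p under 0.05. The count was 342 with array weights and 159 without the arrays AL with RU486 pool 1 and DR with RU486 pool 3. It was 27 with single probes tested.

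On DR the same comparison passed for more transcripts. FBtr0070490 rose by 2.03 ± 0.07 log2 (SE, adjusted p = 3.27e-16), or 4.08-fold, and FBtr0081372 by 1.24 ± 0.14. Without RU486, FBtr0078597 and FBtr0073333 had risen with DR, the former by 3.40 ± 0.36 log2 and the latter, above background on 3 of 6 AL arrays, by at least 3.20. With RU486 on DR the former fell by at least 1.81 and the latter by at least 1.73, each to 5 of 6 arrays above background. The rise and the fall share the DR arrays without RU486, so chance on these arrays enters both. With RU486 both transcripts were still higher on DR than on AL. The measured differences were 1.68 ± 0.36 and 1.46 ± 0.32 log2 (adjusted p = 0.00044 and 0.00046), with some arrays below background on either diet. Their pools were spread widely on DR with RU486, at 9.39 ± 1.15 and 9.07 ± 1.06 log2 (SD, n = 6). Of the 16 transcripts with a symbol, HDAC3 rose by 0.29 ± 0.07 log2 (adjusted p = 0.0091), alpha-Spec fell by 0.46 ± 0.12 (adjusted p = 0.014) and LanA fell by 0.28 ± 0.08 (adjusted p = 0.021), while 13 did not pass. The number that passed was 4 when adjusted over the list alone. The LanA call was lost without pool 5 of the DR group not given RU486 or without pool 3 of the DR group given RU486, with adjusted p of 0.061 and 0.060, and with medians over probes (adjusted p = 0.22). The transcript sle was higher by 0.18 ± 0.06 log2 and did not pass (adjusted p = 0.060). It passed in 4 alternatives (adjusted p from 0.028 to 0.038), 1 of them among 12 fits that left out 1 array.

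For RU486 on DR, 2284 transcripts passed in limma, 990 higher and 1294 lower. At 1.5-fold, 14 rose and 161 fell. After centring on array medians 1392 rose and 1063 fell. The count was 1093 without pool 5 of the DR group not given RU486, 1345 without pool 3 of the DR group given RU486 and 3915 without pool 1 of the AL group given RU486, which enters through the shared estimate of the spread. It was 2984 without the 2 arrays that stand apart, and 374 with single probes tested. Of the 1294 that fell, 1142 (88.3%) had risen in the average diet effect, against 403 for independent lists. Of the 990 that rose, 887 (89.6%) had fallen in it, against 395. Both effects varied with brightness, as given under the other observations, and independent lists leave this out. Across transcripts, Pearson's r of the average diet effect with the RU486 effect was −0.62 on DR and 0.03 on AL. With the average RU486 effect it was −0.53, and between the RU486 effects on AL and DR it was −0.07. Spearman's rho for these 4 pairs was −0.64, 0.03, −0.58 and −0.18. The RU486 effects on AL and DR had the same sign for 44.1% of transcripts.

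**Figure D3:**
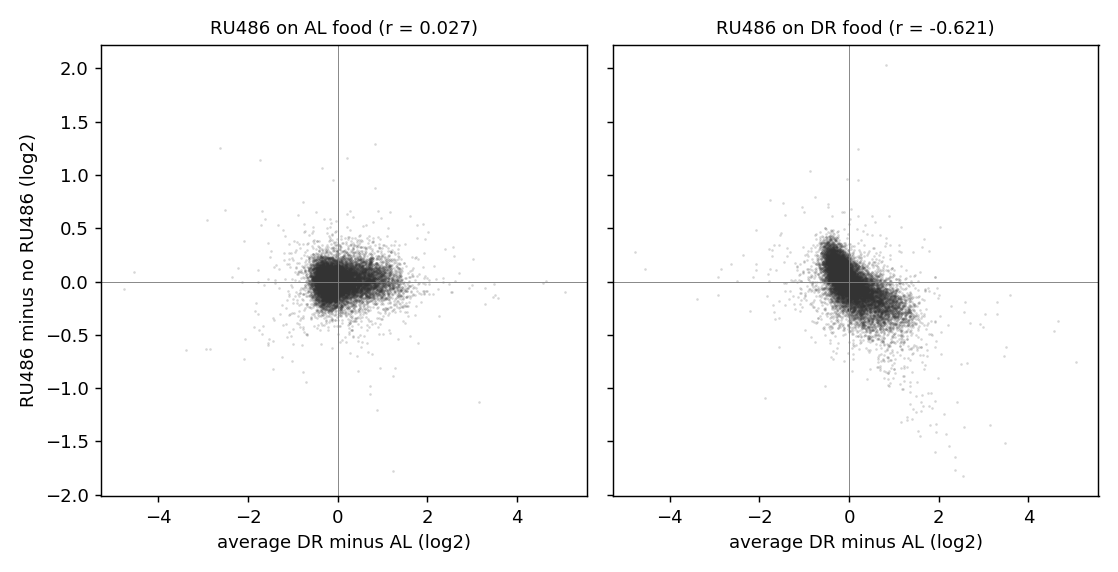
Each point is 1 of 16637 transcripts, with the average DR minus AL difference in log2 on the horizontal axis and the RU486 minus no RU486 difference in log2 on the vertical axis, on AL (left) and DR (right). Pearson's r is 0.03 on AL and −0.62 on DR.

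On the diet axis, where 0 is the AL mean and 1 the DR mean, DR pools lay at 1.14 ± 0.13 without RU486 and at 0.84 ± 0.10 with it (SD, n = 6). The difference was −0.29 (exact permutation p = 0.0022, the smallest possible, adjusted over 2 tests 0.0043), and the groups did not overlap. AL pools lay at 0.005 ± 0.051 without and 0.022 ± 0.028 with RU486, a difference of 0.017 (exact permutation p = 0.51, adjusted 0.51).

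**Figure D4:**
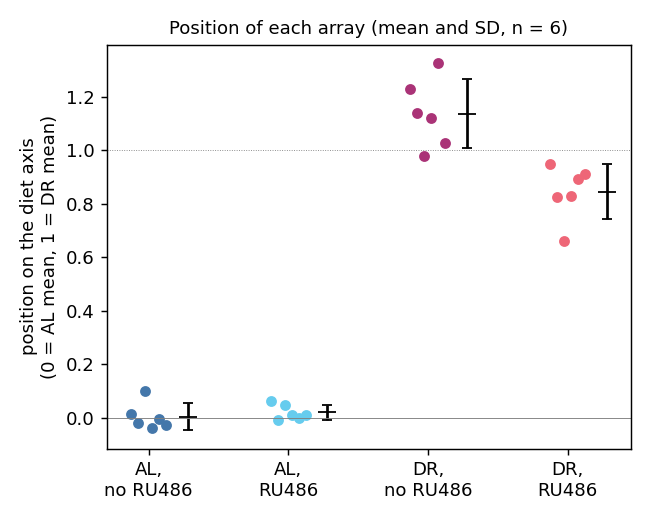
Position of each of the 24 arrays on the diet axis, by group, with mean and SD (n = 6), where 0 is the AL mean and 1 the DR mean. DR pools with RU486 lie between 0.661 and 0.949 and those without between 0.978 and 1.33.

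The interaction asked whether the response to diet differs with RU486. At the upper end the rule for naming took FBtr0080237 (adjusted p = 0.0019), above background on 0 of 6 arrays of AL with RU486 and so at least 1.12 log2, and FBtr0087401, at 0.98 ± 0.14 (SE). FBtr0087401 fell with DR by 2.03 ± 0.10 log2 without and by 1.05 ± 0.10 with RU486. At the lower end it took FBtr0073333, at −1.80 ± 0.45 (adjusted p = 0.019; above background on 3 of 6 arrays in each AL group), and FBtr0078597, at −1.72 ± 0.51 (above background on 5 of 6 arrays in each group with RU486). For these 2 the arrays below background set no bound. The call of FBtr0078597 (adjusted p = 0.044) was lost in 16 of 24 fits that left out 1 array, with adjusted p from 0.051 to 0.071, and with the replicate block (adjusted p = 0.054). None of the 16 transcripts with a symbol passed over all transcripts. Adjusted over the list alone, 2 passed. HDAC3 was at 0.32 ± 0.10 log2 (adjusted p over all transcripts 0.0502). It passed in 11 alternatives (adjusted p from 0.016 to 0.049), 5 of them among the 24 fits that left out 1 array. In the other alternatives HDAC3 did not pass. In 4 alternatives alpha-Spec passed (adjusted p from 0.032 to 0.049), 2 of them among these 24 fits. CG16974 and His4r passed in 1 of the 24 fits each (adjusted p = 0.045 and 0.037).

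In limma 1084 transcripts passed the interaction, 554 higher and 530 lower, or 56 and 193 at 1.5-fold. For 987 of them (91.1%) the interaction opposed the average diet effect, so that the response to diet was smaller with RU486 or turned. The count was 620 without pool 5 of the DR group not given RU486, 1853 without pool 1 of the AL group given RU486 and 1696 without pool 1 of the DR group given RU486. It was 2281 with array weights, 1597 without the 2 arrays that stand apart and 170 with single probes tested.

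Averaged over diets, RU486 raised FBtr0070490 by 1.66 ± 0.05 log2 (SE) and FBtr0081372, above background on 3 of 6 AL arrays without RU486, by at least 1.16. FBtr0087912 fell by 1.24 ± 0.23 and FBtr0080237, above background on 0 of 6 AL arrays with RU486, by at least 0.91. Each of these passed on 1 diet only. On AL the RU486 effect of FBtr0087912 was −1.13 ± 0.32 log2 (adjusted p = 0.14). On DR that of FBtr0080237 was −0.35 ± 0.16 (adjusted p = 0.13). In limma 454 transcripts passed, 119 higher and 335 lower, or 7 and 35 at 1.5-fold, and 845 without pool 1 of the AL group given RU486. The average diet effect passed for 11813, 5178 higher and 6635 lower on DR (2085 and 324 at 1.5-fold), or 4119 and 9390 after centring on array medians. With single probes tested, 4312 rose and 4030 fell.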

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

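The tests of DR with RU486 pool 3 as the only source, of mixed RNA, of probe noise, of the slope along transcripts and of the background shift were chosen or rewritten only after their results or related ones were seen, and the diet axis itself was added after the data were seen.

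Other assignments of the arrays were drawn, 100 for each comparison with the real one included. In each comparison only 1 of the 100, the real one, gave as many transcripts. For the pairwise contrasts this argues against chance at this level. For the interaction and the average RU486 effect, RU486 was shuffled within each diet. For the average diet effect, diet was shuffled within the RU486 groups. Such assignments stand for no effect of the shuffled factor at all, so they do not isolate an interaction or an average. For diet without RU486 the real count was 10860 and the highest other 7636. For diet with RU486 it was 8116 against 5088, for the average diet effect 11813 against 5793, for RU486 on AL 104 against 8 and for RU486 on DR 2284 against 1313. For the interaction it was 1084 against 12 and for the average RU486 effect 454 against 6.

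The response to diet differed with RU486 for 1084 transcripts by the interaction test. Among the transcripts named, the interaction was 0.74 log2 for FBtr0070490, 1.43 for FBtr0080237 (above background on 0 of 6 arrays of AL with RU486, and 1.12 with these set to it), 0.98 for FBtr0087401, −1.80 for FBtr0073333 (above background on 3 of 6 arrays in each AL group) and −1.72 for FBtr0078597. The test also passed at −1.09 for FBtr0073651, which was above background on 0 of 12 DR arrays, so this value is no measured difference between the diet responses. On DR, pools with RU486 lay nearer to the AL pools on the diet axis than pools without it. DR with RU486 pool 3 alone is argued against by the size of the difference, which was −0.255 without it and −0.292 with it. The exact permutation p without it was 0.0043, a value fixed once the groups did not overlap, and so adds nothing. For a compressed signal on these arrays a bound was set beforehand. Over 3842 transcripts with an average diet effect within 0.1 of 0, slopes against DR without RU486 were 0.959 to 1.00. All lay nearer to 1 than to 0.743, the ratio of the axis positions, and so met the bound against compression. The test cannot decide, since a ratio of axis positions need not equal a slope of brightness. The arrays' sorted values also differed by at most 0.38 below the brightest 100 ranks, which by itself keeps such slopes near 1. Whether differences between diets were compressed stays open.

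RNA of AL flies mixed into the DR pools with RU486 is argued against as the whole of this shift. It would give the same share of AL signal from transcripts that rose and from those that fell. The exact permutation p of the difference of the 2 shares, against DR arrays without RU486, was 0.017, 0.0065, 0.0022 and 0.024 at 1.5-fold, 2-fold, 2.83-fold and 4-fold. Over the 6 arrays, risers gave 8.40% to 52.0% and fallers 1.00% to 13.9% at 1.5-fold, which overlap. At 2-fold they gave 8.40% to 52.3% and −1.85% to 5.52%, at 2.83-fold 25.6% to 54.7% and −3.70% to 7.12%, and at 4-fold 25.3% to 60.4% and −2.41% to 3.19%. Of the forms of this test, all chosen after related values were seen, ranges at 4-fold and the permutation at 1.5-fold argued against mixing, and a rule asking also for ranges apart at all 4 thresholds left it open. The level of the 14 fallers at 4-fold lay below that needed on each array by 2.38 to 5.56 SDs of the fallers, but by only 0.91 to 2.08 SDs of that shortfall on DR arrays without RU486, so single arrays do not decide. The form used here, the permutation alone at all 4 thresholds, was chosen last. A small share of AL RNA stays open, since fallers at 1.5-fold gave a mean of 6.32 ± 4.44% (SD, n = 6). The action of RU486 and the transgene, which the design names, also stays open and cannot be separated into drug and transgene.

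Single pools lay far from the rest of their group, by a gap, as a share of the group's range, over Dixon's 95% critical value, for 11 of 116 groups of named transcripts and 4 of 24 groups of array measures, where chance gives about 1 in 20. In AL with RU486, pool 1 was highest for fend (gap 0.710 of the range), mio (0.732), kis (0.751), sle (0.797) and Wdr24 (0.746) and lowest for His4r (0.838). Its SD of deviations (0.882) and its slope of deviations along transcripts (0.738) were also far from the other pools. In DR with RU486, pool 3 had the lowest median (0.810) and the highest SD (0.631). The remaining gaps were 0.652 for His4r in AL without RU486 pool 6, 0.744 for FBtr0072764 in DR with RU486 pool 1, 0.694 for FBtr0078597 in DR without RU486 pool 5, 0.657 for FBtr0081372 in DR with RU486 pool 6 and 0.640 for FBtr0085029 in AL with RU486 pool 6.

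The probe tests put these 2 arrays apart in different ways. A single test for both was split into 1 per array after the values were seen, with its bounds of 0.1 and 0.5 kept. In AL with RU486 pool 1 the probes of 1 transcript deviated together, with a correlation of 0.549, which argues against noise of single probes. Its slope of deviations against probe rank lay 4.64 SDs from the mean of the other 23 arrays, so degraded or unevenly amplified RNA is a candidate explanation. In DR with RU486 pool 3 the correlation was 0.035, consistent with noise of single probes, and its slope was −1.87 SDs from the other arrays, which decides nothing. No biological explanation was tested for either pool.

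The random control probes, which set the background, were lower on DR than on AL arrays without RU486, by −0.16 log2 at their median. Transcripts above background on no array fell with diet too, with a median average diet effect of −0.11 log2 against −0.12 for the random probes. The gap between them of 0.015 log2 is consistent with a lower background on the DR arrays as the source of these calls. No biological explanation was tested for these transcripts. The shift of the random probes was itself smaller with RU486. In limma their median difference between diets was −0.149 log2 without and −0.103 with RU486, and their median RU486 effect on DR was 0.046. Whether such a shift adds to the smaller response to diet with RU486 was not tested and stays open.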

How the results depend on the processing

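Leaving out the arrays that stand apart, restricting to transcripts above background, leaving out arrays of groups not compared, and all alternatives for the diet axis were chosen after the data were seen. Most counts stayed within 1.5 times of the values reported, though not always with the same transcripts. Exceptions were, without transcripts below the 50th percentile, 5607 for diet without RU486, 4175 for diet with RU486, 34 for RU486 on AL, 1355 for RU486 on DR, 6085 for average diet and 91 for average RU486, where fewer transcripts were tested. With single probes tested, a transcript counted only when at least 50% of its probes each passed in 1 direction. The exceptions were then 4692 for diet with RU486, 27 and 374 for RU486 on AL and DR, 170 for the interaction and 62 for average RU486. With array weights they were 342 for RU486 on AL, 2281 for the interaction and 1235 for average RU486. Without the 2 arrays that stand apart they were 159 for RU486 on AL and 750 for average RU486. The single-probe rule asks more of a transcript than the main test, and how far this lowered its counts was not tested. For array weights and the 2 arrays left out, the cause was not tested. With medians over probes, 627 of 1121 interaction calls and 1408 of 1894 for RU486 on DR were among those reported. For diet without RU486 it was 9344 of 10041. With only the 2 groups compared, it was 73 of 106 for RU486 on AL and 1769 of 2308 on DR.

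With 1 array left out, counts ranged from 10277 to 11657 for diet without RU486, 7650 to 8828 for diet with RU486, 73 to 122 for RU486 on AL, 1093 to 3915 for RU486 on DR, 620 to 1853 for the interaction, 11498 to 12406 for average diet and 305 (without pool 3 of the AL group not given RU486) to 845 for average RU486. Pearson's r ranged from 0.890 to 0.917 for the diet effects, −0.12 to −0.04 for the RU486 effects, −0.57 to −0.48 for the average effects, and −0.01 to 0.09 (AL) and −0.66 to −0.58 (DR) for average diet with RU486. Without transcripts below the 50th percentile the RU486 effects had an r of −0.17, beyond the spread, and the cause was not tested. Axis differences ranged from 0.008 to 0.034 on AL and −0.32 to −0.26 on DR, with exact permutation p up to 0.0043 on DR.

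Of 2762 values of named transcripts under alternatives, 2701 kept their side of the threshold, 39 came to pass and 22 no longer passed. The number of called values that changed sign was 0. Changes of sign in values that passed in neither fit were counted among the 2701. Pool numbers were not used as pairs, since deviations of same-numbered pools correlated over 0.1 in only 6 of 36 pairs (median −0.03). Of these, 4 lay among the 6 pairs of AL and DR with RU486, so a partial link there is not excluded. The replicate block gave 10681, 7920, 88, 2047 and 972 transcripts for the 4 pairwise contrasts and the interaction. It ended the FBtr0078597 interaction call and was within 1.5 times for every count. Not run were camera's estimated correlation and the alternatives for ACC, since no list member was named. Signal over background limits what can be said of the 1380 transcripts above it on no array.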

Other observations

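The direction of the diet response varied with brightness, a relation that was looked at only after the data were seen. Among transcripts of intermediate brightness, deciles 4 and 5 by mean value (8.17 to 9.65 log2), 1938 rose and 829 fell with DR without RU486, so that 70.0% of calls were higher. In deciles 6 to 9 (9.65 to 11.88 log2), 1463 rose and 3347 fell, and 30.4% of calls were higher. In decile 1, 24 rose and 681 fell, in decile 2 it was 276 and 416, in decile 3 it was 869 and 194 and in decile 10 it was 376 and 447. The median difference was 0.44 log2 in decile 4 and −0.24 in decile 7. With RU486 the same medians were 0.34 and −0.14 log2. The RU486 effect on DR varied with brightness in the opposite way. In decile 4, 44 transcripts rose and 285 fell with a median of −0.10 log2, and in decile 7, 176 rose and 106 fell with a median of 0.04. The scale of the deposited values across brightness was not given in the sources used here, and no explanation was tested.

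FBtr0070490 was among the named transcripts for RU486 on both diets. All 8 of its probes were higher with RU486 on either diet, by 0.25 to 1.80 log2 on AL and by 0.84 to 2.66 on DR. FBtr0081372 was higher on both diets too, by at least 1.08 log2 on AL, where 3 of 6 arrays without RU486 were above background, and by 1.24 ± 0.14 on DR (SE). Of the transcripts that passed for RU486 on AL, 10 rose and 18 fell on DR as well, against 2.86 and 4.36 for independent lists, while 1 and 3 passed in opposite directions.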
